A study of Mus musculus with 4 samples.

How the data were processed

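ELF1, a transcription factor of the ETS family, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse macrophages grown from bone marrow and treated with lipopolysaccharide (LPS) for 6 h. Per the labels' protocols, sonication gave DNA of 200 to 500 bp, 20 uL of chromatin was kept as input and 100 uL went to immunoprecipitation (IP) with an ELF1 antibody. The series has 4 samples: 1 IP and 1 input library from wild-type (WT) mice, and 1 IP and 1 input library from Elf1 knockout (KO) mice. Groups were taken from the sample titles. The labels give no sex, strain or number of mice. The peak lists of the 2 IP libraries were analysed; reads and signal of the inputs were not analysed here.

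Per the series' design text, the authors trimmed reads with Trimmomatic 0.36, mapped them to GRCm38 with Bowtie2 and removed duplicates with SAMtools rmdup. The submitters' processing notes also name Bowtie2, SAMtools and the builds GRCm38 and mm10, without versions of these tools. The peak caller, its threshold and the annotation tool are not given in the sources used here. As the deposited lists are named, each IP library was set against the input of its own genotype, and peaks were called per library, not on pooled samples. Per the file headers, each peak has a pileup signal at its summit, a fold enrichment, a −log10 p and a −log10 q, together with gene features and the nearest gene. The deposited pileup signal held whole numbers of 5 or more. The deposited fold enrichment equals the ratio of the pileup to a local background, each with a pseudocount of 1 added. That relation was checked through the deposited −log10 p: a Poisson tail at the background so recovered matched within 0.01 for 100% of the 5514 WT and 5544 KO peaks whose tail could be computed. Peak values are the authors' own. They were used only to describe, rank or filter peaks within a list and to describe the strongest shared peaks in both lists.

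Every deposited −log10 p exceeded 3, so the lists behave as if a threshold of 0.001 on p had been applied. The lowest background was 1.00 fragments in the WT list and 1.05 in the KO list. Divided by the narrowest peak width of each list, these give a KO to WT ratio of 1.02. Library totals are not in the peak lists, so read depth itself is unknown. A genome-wide background near 1 fragment per window means that a peak of 5 fragments can already pass. The lists cannot tell low depth from weak enrichment, and either can leave moderate binding out of a list.

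Coordinates are GRCm38, 1-based. Of the 7894 genes named as nearest, 7889 (99.9%) were found by Ensembl identifier in GENCODE M21, and 98.0% of those had identical coordinates. No peak ran past the end of its chromosome. The authors' distance to the nearest transcription start site (TSS) equalled that of the peak midpoint within 2 bp in 100% of peaks. Each peak got 1 annotation class, the first of promoter, 5′ UTR, 3′ UTR, exon, intron and intergenic among the features the authors list. A promoter peak lay within 1000 bp of the authors' nearest TSS. Sequence was read from the GRCm38 reference, with repeats taken from its soft-masking.

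A peak was called shared if it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1), and otherwise WT-only or KO-only. The overlap expected from position alone is the mean of 20 seeded shuffles of the other list within its chromosomes. TSS shares were set against 20 shuffles in the same way. Shares carry exact Clopper-Pearson 95% intervals and medians carry exact order-statistic intervals; chromosome densities carry exact Poisson intervals. All of these cover counting error only. With 1 IP library per genotype there is no replicate, so no p-value between genotypes was computed and no difference has a replicate check. Ratios between the 2 lists, weighed below against explanations, also cover counting error only.

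Fixed gene lists, 24 in number, covered LPS and NF-kB signalling, inflammatory effectors, interferon response, alternative activation, macrophage lineage, described ELF1 targets and the ETS family. They also covered markers of T cells, B cells, neutrophils, erythroid cells, stromal cells and neurons, 8 housekeeping families, and olfactory receptors, vomeronasal receptors and keratins. Each list's count was placed among 10000 seeded random lists of the same size from 21924 protein-coding genes. The ETS site CCGGAAGT was sought on either strand within 100 bp of each summit and set against 864 permutations of its bases that keep 1 CpG and hold neither GGAA nor TTCC. Repeat classes were set by sequence: major satellite by a 12-base match, and CA/GT, GGAAT or telomere repeats where such runs cover at least 50% of the peak.

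Named genes followed a rule: the 20 genes with the highest fold among WT-only promoter peaks, the 10 among KO-only and the 10 among shared ones, leaving out predicted or unnamed genes (names with Gm and digits, Rik, LOC, Mir or Snor), plus up to 4 members of each described list, plus Elf1 and Spi1. Groups, comparisons, lists, the naming rule and most other settings tried were fixed before the data were examined. Those settings were other overlap rules, stricter thresholds, other promoter distances, other chromosome sets, other random lists and other motif windows. The overlap, motif and TSS steps were tested on simulated data, and 100% of planted overlaps, sites and midpoints were recovered. Overlap calls on 5000 simulated peaks had 0 disagreements with a direct count. The midpoints were placed inside the promoter limit by design, so their recovery checks only the computation. Of 400 unplanted simulated gene lists, 0.5% passed the threshold for lists. They held random genes, with a larger share of genes set as having a peak than promoter peaks gave. So 0.5% is not the error rate for the fixed lists. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.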

Results

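ELF1 occupancy was measured by ChIP-seq in bone-marrow-derived macrophages, primary phagocytes differentiated in culture, after 6 h of LPS, the bacterial cell wall component that drives inflammatory (M1) activation. The WT and Elf1 KO genotypes each gave 1 IP and 1 input library, and the peak lists of the 2 IP libraries were compared. The KO list serves as the background of the antibody, since KO cells lack its target according to the labels. There are no replicates, so intervals cover counting error only and no difference between genotypes has a p-value or a replicate check.

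The Elf1 locus itself carried no peak in either genotype. Elf1 spans chromosome 14 from 79481194 to 79582494, and the nearest peak to its TSS lay 460 kb away in WT and 184 kb away in KO. Peak lists measure neither ELF1 transcript nor protein, so the genotype rests on the labels alone. Spi1, which encodes the macrophage ETS factor PU.1, also held no peak (chromosome 2, 91082390 to 91115756), with the nearest one 81.8 kb from its TSS in WT and 1247 kb in KO.

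The antibody yielded about as many peaks in KO as in WT cells. The WT list held 5526 peaks and the KO list 5559. Peaks were narrow, with a median width of 238 bp in WT (quartiles 218 and 281) and 246 bp in KO (224 and 288). They were also shallow: 90.6% of WT and 88.3% of KO peaks had a pileup of at most 8 fragments, and the median authors' fold enrichment over input was 3.50 in WT and 3.42 in KO. Few passed a q of 0.05, namely 284 WT peaks (5.14%) and 313 KO peaks (5.63%). The median peak had an authors' q of 0.525 in WT and 0.484 in KO.

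The first question was which WT sites depend on ELF1, taken as WT peaks that no KO peak overlaps. By that measure 5471 WT peaks (99.0%, 98.7 to 99.2, exact Clopper-Pearson) were WT-only. The mirror count was the same size: 5504 KO peaks (99.0%, 98.7 to 99.3) had no WT peak. Only 55 peaks were shared, against 6.0 ± 2.4 (SD of 20 shuffles) when KO positions were shuffled within chromosomes. Among peaks with q above 0.05, 13 of 5242 WT peaks were shared, against 5.7 ± 2.2 in the shuffles, whose highest count was 10.

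Sharing rose steeply with peak strength, so the strongest sites were those found with and without ELF1. Of WT peaks with q of 1e-05 or below, 40 of 54 (74.1%, 60.3 to 85.0) overlapped a KO peak, and of KO peaks 40 of 46 (87.0%, 73.7 to 95.1) overlapped a WT peak. At a fold enrichment of 10 or more, 23 of 24 WT peaks (95.8%, 78.9 to 99.9) and 22 of 22 KO peaks were shared. Between q of 0.05 and 1e-05, only 2 of 230 WT and 2 of 267 KO peaks were. The median fold was 4.74 (3.57 to 14.9) in shared and 3.50 in WT-only peaks of the WT list, and 4.88 (3.42 to 17.3) in shared and 3.42 in KO-only peaks of the KO list.

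**Figure D1:**
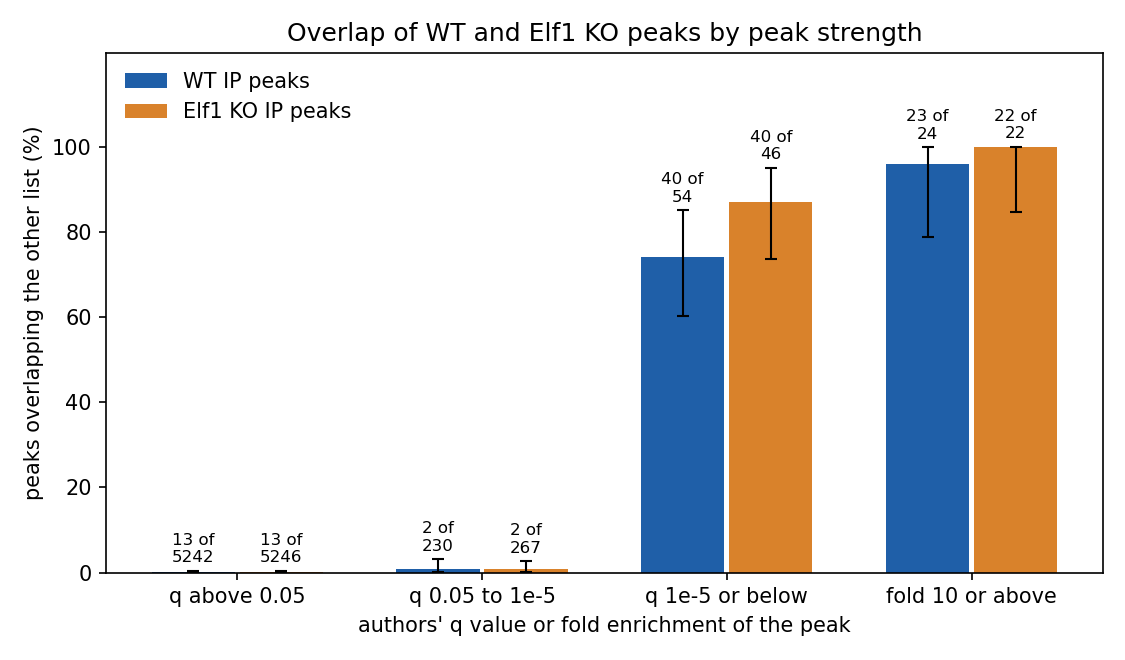
Percentage of WT IP peaks (blue) and Elf1 KO IP peaks (orange) that overlap a peak of the other list by at least 1 bp, by the authors' q value and, at the right, for peaks of fold enrichment 10 or above, which also belong to the q classes. Error bars are exact Clopper-Pearson 95% intervals and the numbers are shared peaks of all peaks. The share is 74.1% (WT) and 87.0% (KO) at q of 1e-05 or below, and under 1% at weaker q.

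The strong sites were mostly simple repeats. Of the 24 WT peaks with a fold of 10 or more, 21 lay in CA/GT dinucleotide repeats, 1 in a GGAAT repeat and 2 in genes of the 7SL RNA, the RNA of the signal recognition particle. In KO, 21 of 22 lay in CA/GT repeats and 1 in the GGAAT repeat. The peak of highest fold in both lists was the intergenic GGAAT repeat on chromosome 17 (4626166 to 4626591), with a fold of 159.6 in the WT and 124.0 in the KO list. Next in the WT list was an intergenic CA/GT repeat on chromosome 14 (99464784 to 99465080) at 100.1. The 7SL genes Rn7s1 (peak at chromosome 12, 69159304 to 69159585) and Rn7s2 (69361191 to 69361463) reached 15.5 and 12.3 in the WT list and 7.59 and 7.31 in the KO list. These sites do not stand for the rest. Over the 23 shared WT peaks of fold 10 or more, the KO fold was higher at 14 and the WT fold at 9. The medians were 27.7 in WT and 29.4 in KO. The only WT peak of that strength with no KO overlap was a further intergenic CA/GT repeat (chromosome 10, 80464309 to 80464517), at a fold of 16.0. Major satellite, the pericentromeric repeat, gave 13 WT and 16 KO peaks with pileups up to 31738 and 34053. Folds were at most 2.13 in WT. In KO they were at most 2.15 in the 15 peaks with q of 1e-05 or below. The remaining KO peak, of 5 fragments and q above 0.05, had a fold of 2.93. Repeat-masked sequence made up a median of 100% of shared peaks and 22.9% of WT-only and of KO-only peaks.

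Peaks found in only 1 genotype lay mostly away from genes, in like proportions in WT and KO. Intergenic positions took 58.1% of WT-only peaks (56.7 to 59.4) and 58.6% of KO-only peaks (57.3 to 59.95). Introns took 37.1% of both. The authors' promoter class held 148 WT-only peaks (2.71%, 2.29 to 3.17) and 126 KO-only peaks (2.29%, 1.91 to 2.72), intervals that overlap. Exons held 1.28% and 1.42%, and 3′ UTRs 0.80% and 0.49%. Among the 55 shared peaks, 9 (16.4%, 7.77 to 28.8) were in the promoter class. All 9 lay in major satellite, in a CA/GT repeat or in genes of the signal recognition particle RNA.

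Proximity to genes was below that of shuffled positions in both genotypes. Within 1000 bp of any GENCODE TSS lay 146 WT-only peaks (2.67%, 2.26 to 3.13), against 3.91% of shuffled positions, and 132 KO-only peaks (2.40%, 2.01 to 2.84), against 3.61%. For TSSs of protein-coding genes the shares were 0.93% against 1.61% in WT and 0.82% against 1.47% in KO. Of the 242 WT-only peaks with q below 0.05, 10 (4.13%, 2.00 to 7.47) lay within 1000 bp of a TSS, and of the 271 such KO-only peaks 6 (2.21%, 0.82 to 4.76).

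**Figure D2:**
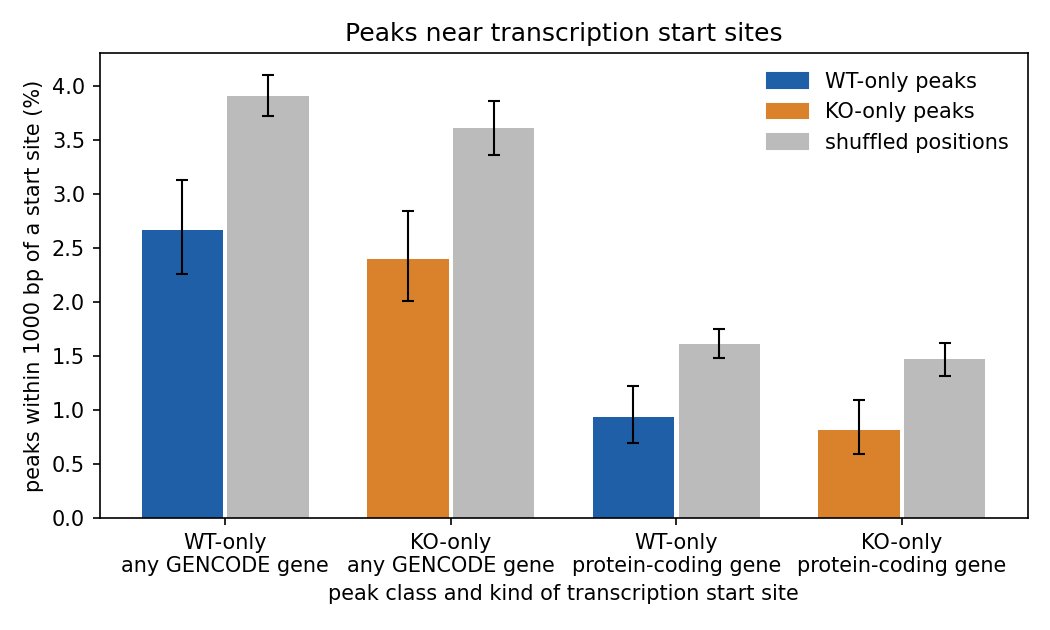
Percentage of WT-only (blue) and KO-only (orange) peaks whose midpoint lies within 1000 bp of a transcription start site, for any GENCODE gene and for protein-coding genes, beside shuffled positions (grey). Error bars are exact Clopper-Pearson 95% intervals for peaks and the SD of 20 shuffles for shuffled positions. All 4 peak bars stand below their shuffled bars, for example 2.67% against 3.91% for WT-only peaks and any gene.

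Promoter peaks named few genes in either genotype. In WT 154 genes had a promoter peak, 54 of them protein-coding, and in KO 139 genes, 51 of them protein-coding. WT-only promoter peaks covered 144 genes (47 protein-coding) and KO-only promoter peaks 129 (44 protein-coding). The 10 genes with promoter peaks in both lists were all predicted Gm genes, among them Gm10800 and Gm10801, so the rule named no gene for shared promoters. With the promoter limit at 500 bp the WT-only and KO-only counts were 73 and 60, and at 5000 bp 683 and 673.

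With predicted or unnamed genes left out, the WT-only promoter peak of highest fold lay in an intron of Zfp979, a zinc-finger gene, 571 bp past the TSS (chromosome 4, 147641815 to 147642070), with a fold of 6.998 and −log10 q of 6.16. Akr1c18, which encodes a 20-alpha-hydroxysteroid dehydrogenase, followed with a fold of 5.50 and −log10 q of 2.91 at 731 bp upstream (chromosome 13, 4151268 to 4151503). The vomeronasal receptor Vmn1r157 had 4.80 and the pseudogene Obox3-ps7 4.49. At 4.47 stood Lrrtm3, a synaptic leucine-rich repeat gene, the mast cell protease pseudogene Mcpt-ps1 and Mrgprb8, a Mas-related G protein-coupled receptor gene. Kdm4c, a histone H3K9 demethylase gene, had 4.39. The remaining 12 ran from 4.00 to 3.50: Zfp87, Ubd (the ubiquitin-like modifier FAT10), Arhgap15os, Olfr259, Zfp987, Olfr958, Auh (an RNA-binding enoyl-CoA hydratase), Olfr873, Spag16, Taf15, Phf11c and AC154464.1. Peaks tied at 3.50 were more than the places left and were taken in order of significance and position.

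Among KO-only promoter peaks, likewise without predicted or unnamed genes, Olfr1301 had the highest fold, 4.39, with a −log10 q of 1.06 (chromosome 2, 111750425 to 111750636). Among the others, Tmem88b, Ppargc1a (a coactivator of mitochondrial biogenesis), Strn4, Hspd1-ps1, Iqcf1 and Stx19 had 3.90, Defb13, a beta-defensin gene, had 3.88 and Ttc26 had 3.54. None of these KO-only peaks passed a q of 0.05.

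No gene of the inflammatory or macrophage lists had a promoter peak in either genotype. The counts were 0 of 38 measured genes of LPS, TLR4 and NF-kB signalling, 0 of 37 inflammatory effectors, 0 of 37 interferon and antiviral genes, 0 of 28 genes of alternative activation, 0 of 34 macrophage lineage genes, 0 of 28 described ELF1 targets and 0 of 27 ETS family genes. Together these 7 lists hold 223 genes, and 58.5% of random lists of 223 genes also had 0 in WT, so a count of 0 does not set these promoters apart from others. Marker lists of other cell types were likewise at 0: 18 T cell, 16 B cell, 18 neutrophil, 15 erythroid, 18 stromal and 22 neuronal genes. So were 95 cytosolic and 78 mitochondrial ribosomal protein genes, 39 proteasome, 36 complex I, 43 ATP synthase and cytochrome oxidase, 44 splicing, 55 translation initiation and 95 histone genes, and 49 keratins. These counts go by the nearest TSS: the strong Rn7s1 peak, nearest to a predicted Gm gene, also lay 258 bp upstream of the TSS of the ribosomal gene Rps29 in WT and 256 bp upstream in KO. Over the 8 housekeeping families, 485 genes, 29.9% of random lists had 0 in WT.

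Chemosensory receptor genes, which are silent in most tissues, were the only ones of the 24 lists with promoter peaks by the nearest TSS. WT-only promoter peaks lay at 8 of 1092 olfactory receptor genes, led by Olfr259 and Olfr958 (fold 4.00), Olfr873 (3.79) and Olfr1249 (3.50); 0.29% of random lists reached that count. KO-only promoter peaks lay at 6 of them, a count that 2.11% of random lists reached. WT-only promoter peaks lay at 4 of 326 vomeronasal receptor genes, Vmn1r157 (4.80), Vmn1r10 (3.50), Vmn1r123 (3.50) and Vmn2r53 (3.00), reached by 0.54% of random lists, and KO-only ones at 2, reached by 13.6%. These promoters are AT-rich: the median GC content within 500 bp of the TSS was 36.4% in olfactory and 37.3% in vomeronasal receptor genes, against 54.7% in all protein-coding genes. Among random lists matched on promoter GC, 78.2% reached the olfactory and 32.6% the vomeronasal WT-only count.

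The ELF-type ETS site was rare in every class of peak. CCGGAAGT lay within 100 bp of the summit in 7 of 5471 WT-only peaks (0.128%, 0.051 to 0.263), 3 of 5504 KO-only peaks (0.055%, 0.011 to 0.159) and 0 of 55 shared peaks (upper bound 6.49%). Control 8-mers averaged 0.050% in WT-only peaks, a ratio of 2.57 (1.04 to 5.30), and 45 of the 864 controls were at least as frequent as the site. In KO-only peaks the ratio was 0.94 (0.19 to 2.73), and the WT-only and KO-only intervals overlap. Shuffled WT-only positions held the site in 0.102% of windows and shuffled KO-only positions in 0.134%. Shuffled positions were not matched on base composition. All 7 WT-only peaks with the site lay more than 1000 bp from a TSS. Other macrophage motifs were as frequent in WT-only as in KO-only peaks within counting error: PU.1 sites in 1.55% (1.24 to 1.92) and 1.36% (1.07 to 1.71), AP-1 sites in 2.85% (2.43 to 3.33) and 2.91% (2.48 to 3.39), NF-kB sites in 0.82% (0.60 to 1.10) and 0.98% (0.74 to 1.28) and interferon response elements in 3.71% (3.23 to 4.25) and 3.69% (3.21 to 4.22).

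The sex chromosomes set the lists apart. Autosomes carried 2.21 peaks per Mb in WT and 2.14 in KO. The X chromosome carried 0.593 per Mb in WT (0.481 to 0.724) and 2.65 in KO (2.41 to 2.92), and the Y chromosome 1.51 in WT (1.26 to 1.79) and 0.091 in KO (0.039 to 0.179). On autosomes alone, 99.0% of WT peaks and 98.9% of KO peaks lacked a peak in the other list.

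**Figure D3:**
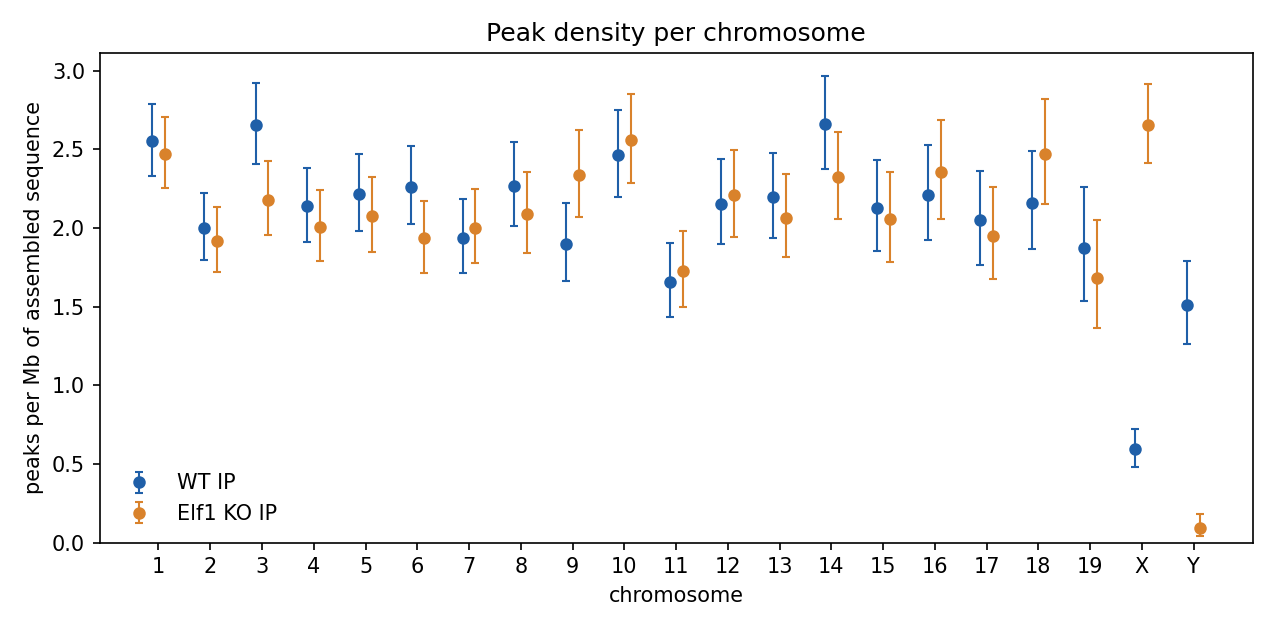
Peaks per Mb of assembled sequence on each chromosome in the WT IP (blue) and Elf1 KO IP (orange) lists, with exact Poisson 95% intervals. Autosomes range from 1.66 to 2.66 in WT and from 1.68 to 2.56 in KO, while X stands at 0.593 and 2.65 and Y at 1.51 and 0.091.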

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

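All tests on the sex chromosomes and on repeats were chosen only after the result was seen, as was the ratio of WT-only to KO-only peaks; those on ETS sites and on TSS proximity were planned.

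The WT and KO lists shared about 1% of their peaks. If ELF1 binding made up most WT-only peaks, they would outnumber KO-only peaks; the ratio was 0.994 (0.957 to 1.03), which argues against it. Chance pile-ups of background fragments are a candidate explanation: WT-only peaks lay near a TSS 0.683 times as often as shuffled positions (0.578 to 0.801), where excess would have counted against chance. Placement was not uniform, however: that interval lies below 1, and 13 weak WT peaks were shared against at most 10 in the shuffles. Of those 13, 10 lay in repeat-masked sequence outside the named repeat classes, which held 27.2% of WT peaks with q above 0.05. Whether a minority of ELF1 sites is among the WT-only peaks stays open. The 7 peaks with ELF-type sites gave 2.57 times the control mean (1.04 to 5.30, spanning the threshold of 3). Their share was 0.128%, against 0.102% of shuffled positions. KO-only peaks had 0.055% (0.011 to 0.159), against 0.134%. Shuffled positions cannot decide it, since on autosomes their median GC content was higher, 41.7% against 37.1% in WT and 41.8% against 39.0% in KO. None of the 7 peaks passed a q of 0.05.

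Signal outside the autosomes drew attention because it exceeded that of the other genotype. The KO list held 434 peaks on X against 97 in WT, and the WT list 133 peaks on Y against 8 in KO. A difference in depth would move X and autosomes alike, yet the KO to WT ratio on X was 4.62 times that on autosomes (3.70 to 5.82). The WT X density was 0.269 of the autosomal one and the KO density 1.24, which is consistent with male WT and female KO mice; the labels give no sex, so sex and genotype would then be confounded. No biological effect of ELF1 on X or Y was tested.

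The WT list held 8 mitochondrial peaks and the KO list 0, with WT folds of 1.25 to 1.62 over a median background of 145 fragments.

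The strongest peaks lay at repeats in both genotypes. Binding by ELF1 that the knockout removes is argued against, since 95.8% of WT peaks of fold 10 or more overlapped a KO peak. Repeat copies collapsed in the reference are consistent with the major satellite peaks, whose implied input background was 5769 times the genome-wide one. They are argued against for the 26 WT CA/GT peaks of any fold, whose median input background was 1.2996 times the genome-wide one and at most 5.06 times, where a p of 0.001 would have allowed a median of 38.1 times. DNA of another organism in the IP libraries could raise repeats shared between species and cannot be told apart, because the GGAAT repeat peak was in both of the 2 IP libraries and no foreign sequence can be sought in peak lists; capture of such fragments by antibody or beads was not tested.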

How the results depend on the processing

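Alternatives on autosomes alone, q below 0.05, gene bodies, any GENCODE TSS and shuffles without assembly gaps were chosen after seeing the data; the rest were planned. Of 65 alternative values, 40 stayed near the reported one (shares and medians inside its 95% interval, counts within 1.5 times) and 25 moved. A reversal could be scored only for the shared over the WT-only or KO-only median by −log10 p or −log10 q, where 0 reversed. For all other values no reversal was defined. WT-only and KO-only shares stayed at 98.7% to 99.2% under other overlap rules, chromosome sets and without the widest 1% of peaks. They were 98.2% and 98.1% for the more significant 50% of a list, and 98.2% for both when the strongest peaks of each list were compared, as many as 50% of the shorter list. They fell to 85.2% and 86.6% at q below 0.05, and to 25.9% and 13.0% at −log10 q of at least 5 in both lists. The last threshold leaves by construction only peaks of q of 1e-05 or below, of which most were shared. The shared median over the WT-only median was 15.9 by −log10 p and 211 by −log10 q in place of fold, and 17.5 and 201 in the KO list; these are other scales. At q below 0.05 the promoter share was 4.13% of WT-only and 1.85% of KO-only peaks, from 10 and 5 peaks. Genes with a WT-only promoter peak numbered 73 at 500 bp, 683 at 5000 bp and 68 in the more significant 50%. Gene lists above random numbered 2 as reported, 0 with GC-matched random lists, 1 with random lists from genes named in either list, 0 in the more significant 50% and 1 by gene bodies. With GC matching the random lists themselves held more promoter peaks; the cause of the other changes was not tested. The longer ETS site gave 0% in WT-only and 0% in KO-only peaks, and promoter peaks alone also 0% and 0%, from 145 and 131 peaks. With a reciprocal overlap of 50% the median fold of shared peaks was 7.83 in WT and 6.67 in KO, inside the wide intervals of the reported 4.74 and 4.88. Few fragments stand behind each peak (median pileup 6 in WT, 7 in KO).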

Other observations

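All tests here, namely the counts over gene bodies, base composition and windows, were chosen only after the result was seen, as were the genes named by gene body.

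Peaks within a gene body or 5000 bp of it touched as many genes in KO as in WT, 1626 and 1633 of 21924 protein-coding genes, and these genes were long (median 105 and 95.5 kb, against 17.4 kb for all). The 8 housekeeping families had such a peak at 7 of 485 genes in WT and 8 in KO, against random means of 36.05 and 35.93. The 6 lists of other cell types had one at 8 of 106 in WT and 7 in KO, against 7.83 and 7.86. Random lists were not matched on gene length. Like the housekeeping families, the macrophage and ELF1 lists fell below random lists, which averaged 16.6 in both genotypes. Such a peak lay at 9 of their 223 genes in WT and 7 in KO. In WT these included Mapk14 (p38 alpha, fold 2.96), Hif1a (3.43), Stat6 (3.50), Cd36 (3.32), Arg1 (3.21), Adgre1 (F4/80, 2.89), Elk3 (3.48) and the described ELF1 targets Tek (4.00) and Cd247 (3.45). In KO they included Tlr4 (3.42), Traf6 (3.30), Zbp1 (3.42), Mertk (3.41), Spic (3.44), Etv5 (3.44) and again Tek (4.19). The strongest peak at each of these genes overlapped no peak of the other list. That was true of 99.0% of all peaks in each list, so it does not set these genes apart. Their pileups were 5 to 8 fragments. The highest −log10 q among them was 0.977 (Tek in KO), so none passed a q of 0.05.

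Vomeronasal receptor genes differed between the lists by the same measure, with a peak at 39 of 326 in WT and 16 in KO. Random lists averaged 24.2 in WT and 24.1 in KO, and 0.19% of them reached the WT count and 97.1% the KO count; the difference between genotypes was not tested. These random lists were not matched on GC content. Matching on promoter GC was done only for promoter counts, where 32.6% of random lists reached the WT-only count of the same family. That result does not bear on the count by gene body. Vomeronasal receptor genes had a median length of 10.5 kb, against 17.4 kb for all protein-coding genes. On chromosome 7 alone, 18 such genes had a WT peak and 6 a KO peak. Olfactory receptor genes had 55 and 57 of 1092, below the random means of 81.4 and 81.2, and their median length was 5.99 kb. Among neuronal genes, which include very long ones, 5 of 22 had a WT peak and 6 of 22 a KO peak, led in WT by Nlgn1 (fold 4.45, 7 peaks).

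Autosomal peaks of only 1 list were AT-rich in both genotypes, and more so in WT. The median GC content was 37.1% in WT (36.9 to 37.3) and 39.0% in KO (38.8 to 39.2), against 41.7% and 41.8% at shuffled positions. Across 501 autosomal windows of 5 Mb, the difference between WT-only and KO-only counts had a standard deviation of 1.02 times its counting error, and 1 window differed by more than 3 times that error.

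Of the 14 WT-only peaks with q of 1e-05 or below, 11 lay mostly in repeat-masked sequence. The other 3, chosen after their values were seen, were the Zfp979 peak, a mitochondrial peak and an intergenic peak on chromosome 3 (5860400 to 5860612, fold 2.51).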
